A study of Mus musculus with 8 samples.

How the data were processed

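Bulk RNA-seq was available for 8 libraries from mouse bone marrow, 5 from Nup214fl/fl mice (control) and 3 from Nup214fl/fl,Mx1-Cre mice (knockout). Groups and replicate numbers were taken from the submitters' genotype labels and titles. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, part of which may be technical. Per the labels' protocols, haematopoietic stem cells were isolated by flow cytometry in the gate CD48-CD150+LSK (lineage-negative, Sca-1-positive, Kit-positive) 3 days after pIpC, a synthetic double-stranded RNA that induces interferon and so the Mx1-Cre recombinase. Total RNA was extracted with a miRNeasy kit, the mRNA was reverse-transcribed and amplified by Geo-seq, a protocol for small numbers of cells, and libraries were made with a TruePrep transposase kit, per the labels' protocols.

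The deposited table gave FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments) for 52097 Ensembl genes in each library, with no counts. The submitters' processing notes name Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2 and the genome build mm10, without saying which tool made which value. The annotation release, any filter and the strand setting were not given in the sources used here. The values were not whole numbers, and each library summed to between 802952 and 1026427 FPKM. FPKM is relative to the mapped total of its own library, so a few genes that take a large share lower the value of every other gene. Without a stated strand setting, antisense and overlapping genes could not be told apart. Genes with near-identical copies, such as Hba-a1 and Hba-a2, the ferritin and ribosomal protein genes with their pseudogenes, and the mitochondrial genes with their nuclear copies, have uncertain values.

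The depth was not stated. In genes with 1 annotated transcript of 600 to 2500 nt, low values multiplied by transcript length, shortened by 200 to 325 nt for fragment size, fell on whole multiples of a step, within a tolerance of 0.15 fragments, for 83.4% to 92.8% of values, against 30% by chance. In units of 1000000 fragments, the step gave an estimated depth of 44.0, 33.9, 29.2, 19.9 and 28.3 in control replicates 1 to 5 and 16.1, 22.5 and 22.2 in knockout replicates 1 to 3. At these depths 1 fragment in a transcript of 1 kb was worth between 0.0227 and 0.0619 FPKM. A gene listed at 0 in every library of a group is given no fold change, and named genes listed at 0 in a single library are named as such; their fold changes depend on the pseudocount.

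Symbols were matched to all 52097 gene identifiers, and coordinates and transcript lengths were taken from GENCODE M21 on GRCm38, the assembly that mm10 names. Where 1 symbol had several identifiers (72 symbols), gene lists used the one with the highest mean. Nuclear copies of mitochondrial genes were found with BLAST+ 2.17.0 as pseudogenes with at least 50% of their length aligned to a mitochondrial transcript at 90% identity or more; 9 were found.

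Knockout and control libraries were compared with limma 3.58.1 in R 4.3.3 (limma-trend, robust empirical Bayes) on log2(FPKM + 1), for the 15121 genes with an FPKM of at least 1 in at least 3 libraries. P-values were adjusted by the Benjamini-Hochberg method over those genes, with a threshold of 0.05. All fold changes are knockout minus control on the log2(FPKM + 1) scale, which understates the change of low genes. The targeted gene was also compared by an exact two-sided permutation test over the 56 ways to choose 3 of 8 libraries, for which the smallest possible p is 0.0179. The 33 gene lists were written before the data were examined and held 705 different genes, of which 1 was not found in the table and 6 list entries were matched by an older symbol. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, then with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. The lists were adjusted together.

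The rule for naming genes was set before the data were examined. It took Nup214, Nup88 and Nup62, the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap and whose mean log2(FPKM + 1) was at least 2, without predicted gene models, and the 3 members with the smallest p in each list. Results of 2 genes that this rule named are not reported here and were left out of the search for libraries far from their group. Kit, Ly6a, Slamf1, Cd48, Procr, Fth1, Ftl1, Gpx4, Acsl4, Cdkn1a, C1qa, Cd3e, Gzma, Cxcl10, Ccl5, Adipoq, Lpl, Apoe, Ctsd, Ctsb, Il2rb, Cldn5 and Bgn were added after their values had been seen, as were Cd163, Xpo1 and other members named to resolve a small count. The model was tested on simulated data with the means and spreads of these 15121 genes, 200 of them changed. Over 5 draws it recovered 43.0% of 2-fold and 86.4% of 4-fold changes, 5.83% of its calls were false, and 0 had the wrong sign. A list shifted by 1 log2 unit was found in 5 of 5 draws. The simulated genes varied independently, and their changes were balanced between rises and falls. The real genes were correlated and mostly fell, so these rates need not hold for the data.

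Alternatives set before the data were examined were leaving out each library, a replicate block, no filter, a filter at an FPKM of 5, quantile normalization, median-ratio rescaling (each library divided by its median ratio to the geometric mean over genes at an FPKM of 1 or more in all libraries), sample quality weights, limma without a trend, pseudocounts of 0.1 and 0.5, other thresholds, and other list tests. Rescaling to the summed FPKM of genes that are neither mitochondrial nor their copies, a covariate for the share of genes under 150 nt listed above 0, and leaving out genes under 300 nt were added after the data had been seen. Count models planned for a table of counts were not run. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

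Tests of explanations for the patterns were revised after their results had been seen in 2 cases. A test set beforehand used all measured members of 4 further cell type lists, and all 4 met it. It was dropped because the filter admits genes that are low in controls mainly when they are high in knockouts. It was replaced by a test on members with a control mean of at least 1 FPKM, for macrophage, T and NK, and endothelial genes together and for reticular and fibroblast genes apart, since these last did not meet the same criterion. The test of nuclear-retained RNA first compared its median with that of all genes alone and was left undecided for the wide spread of its members. It was then compared with the rise of the mitochondrial genes, which addresses only a whole cause.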

Results

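RNA was sequenced from CD48-CD150+LSK bone marrow cells, the sorting gate for haematopoietic stem cells, 3 days after pIpC. Whether the sort gave cells of equal purity in both groups was not stated in the sources used here, so group differences may include differences in the cells collected. The 8 libraries were 5 controls, in which both Nup214 alleles carried loxP sites without Cre, and 3 knockouts, in which the interferon-inducible Mx1-Cre had been switched on. NUP214 is a nucleoporin on the cytoplasmic face of the nuclear pore, where it forms a subcomplex with NUP88 and NUP62. The comparison addressed how loss of Nup214 alters gene expression in normal stem cells. Only the knockouts carried Cre, so effects of Cre itself cannot be told apart from those of Nup214 loss. The study's title concerns leukaemia stem cells and ferroptosis, a form of cell death driven by iron and lipid peroxidation. The estimated depth, in units of 1000000 fragments, was 31.0 ± 8.80 in controls (SD, n = 5) and 20.3 ± 3.59 in knockouts (SD, n = 3; exact two-sided permutation p = 0.107).

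Nup214 was lower in all 3 knockout libraries than in any control. Its FPKM was 43.2, 65.2, 48.5, 34.2 and 55.3 in control replicates 1 to 5 and 17.6, 9.66 and 18.2 in knockout replicates 1 to 3. The means were 49.3 ± 11.8 (SD, n = 5) and 15.2 ± 4.76 (SD, n = 3), a log2 fold change of -1.66 ± 0.25 (SE; limma adjusted p = 0.000289). The exact two-sided permutation test gave p = 0.0179, the smallest it can give. Nup214 (ENSMUSG00000001855) lies on chromosome 2 from 31974436 to 32053975 on GRCm38. The values cover the whole gene, the deleted exons were not given in the sources used here, and transcripts that keep the remaining exons still count. The fall was not specific to the target: 91 of the 500 genes nearest to Nup214 in control mean fell more, and their median log2 fold change was -1.13. After median-ratio rescaling the change was -0.72 ± 0.26 (SE; adjusted p = 0.0538): the fold was smaller with about the same error, and the call ended. It was -0.76 (adjusted p = 0.0415) with quantile normalization and -0.89 (adjusted p = 0.0238) with rescaling to the non-mitochondrial total.

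As deposited, most of the genes tested differed between the groups, whereas the 3 rescalings called between 5397 and 5723 genes. Of 15121 genes tested, 10345 changed, 1348 higher and 8997 lower in the knockout, and 1061 of the higher and 5782 of the lower genes changed at least 2-fold. The groups did not overlap in 9432 genes, against the 3.57% of genes that chance gives, and 9266 of these were among the changed genes. The median log2 fold change of all genes was -0.81, a level of 0.572 of the control, and it depended on scaling. With median-ratio rescaling the median was -0.02 and 2877 genes were higher and 2520 lower, with quantile normalization 2530 and 3079, and with rescaling to the non-mitochondrial total 2310 and 3413, so that 13% of calls were higher as deposited against 53.3%, 45.1% and 40.4%. Without a filter, 30.3% were higher and the median was 0.05. Camera without a filter therefore compared each list with a background at 0.05, so the general fall alone can make a list pass downward. Under all 4 scalings, 1319 genes were called higher and 2511 lower. Mitochondrial genes and their copies were left out of the non-mitochondrial rescaling and so could not be among these. Without knockout replicate 1, 2 or 3, the count of higher genes as deposited was 942, 847 and 860, of 14424, 14451 and 14421 genes tested. The filter still asked for 3 libraries, so genes expressed only in knockouts could no longer pass, and these counts also reflect the filter. Changes of gene groups are therefore given as deposited, to be read against this median, with the counts after median-ratio rescaling.

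The mitochondrial genome took a much larger share of the knockout libraries. Its 37 genes made up 5.97% ± 0.695 of summed FPKM in controls (SD, n = 5) and 41.3% ± 3.02 in knockouts (SD, n = 3; exact two-sided permutation p = 0.0179, the smallest possible). With 9 nuclear copies of mitochondrial genes the shares were 8.08% and 54.5%. All 13 mitochondrial protein-coding genes rose, with a median log2 fold change of 3.23 (camera adjusted p = 8.7e-23; adjusted p = 0.182 with an estimated correlation). Expression of mt-Nd4, a subunit of respiratory complex I, went from 1118 ± 198 to 12365 ± 905 FPKM, and of mt-Cytb, a subunit of complex III, from 2977 ± 491 to 27795 ± 2943 FPKM. The tRNA genes mt-Tl2 and mt-Tn were also among the 10 largest rises, but mt-Tl2 was listed at 0 in all 5 controls and mt-Tn in control replicates 3 and 4. The call of mt-Tn (adjusted p = 0.0311) ended without any 1 of the knockout libraries (adjusted p = 0.0848, 0.0515 and 0.0775 without replicates 1 to 3). These tRNA genes are very short, and their FPKM is correspondingly uncertain. All 13 protein-coding genes also rose after median-ratio rescaling and 11 of them with quantile normalization. Olfactory receptor genes, which blood cells are not known to use, summed to between 23.4 and 167 FPKM in controls and between 480.0 and 663 in knockouts, over 1406 genes. The number of genes at an FPKM of at least 1 was 14091 in controls and 15624 in knockouts (exact two-sided permutation p = 0.0179).

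**Figure D1:**
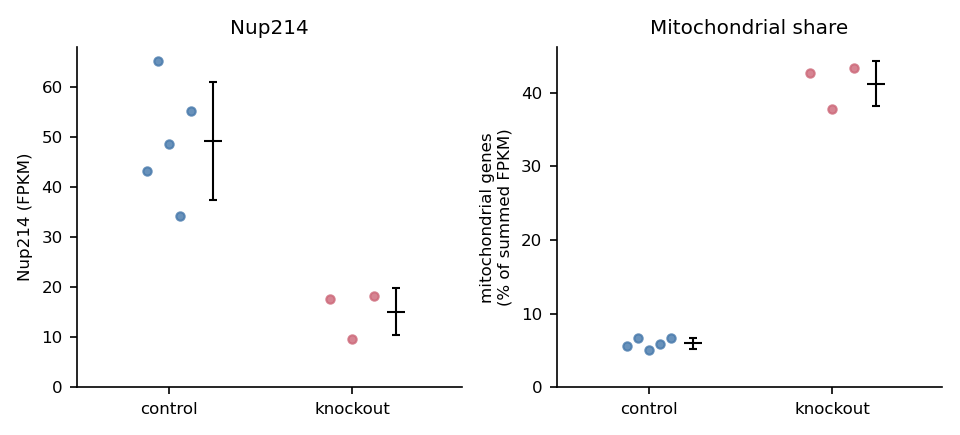
Nup214 expression in FPKM (left) and the percent of summed FPKM from mitochondrial genes (right) for each library; points are the 5 control and 3 knockout libraries, and bars show the mean ± SD. Nup214 ranged from 34.2 to 65.2 in controls and from 9.66 to 18.2 in knockouts, and the mitochondrial share from 5.02% to 6.66% and from 37.8% to 43.3%.

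Genes that mark stem and progenitor cells were lower in the knockout. Of 32 stem cell genes, 23 fell, 2 rose and 7 did not pass, with the same counts adjusted over the list alone; of 20 genes of multipotent and myeloid progenitors, 12 fell, 1 rose and 7 did not pass, also adjusted over the list alone. Meis1, a transcription factor needed by stem cells, went from 118 ± 17.2 to 7.39 ± 3.75 FPKM (log2 fold change -3.95 ± 0.30, SE, adjusted p = 9.07e-06), Hlf from 37.8 ± 11.9 to 1.54 ± 1.12 (0.99 without knockout replicate 3), and Gfi1b, a repressor of the stem and megakaryocyte-erythroid lineages, from 36.9 ± 6.12 to 3.52 ± 2.20. The list medians were -1.72 and -2.60, or -0.92 and -1.79 relative to all genes. Neither list passed camera (adjusted p = 0.314 and 0.259, or 9.82e-07 and 2.81e-06 without a filter). Fry gave adjusted p = 0.000225 and 0.000106, but it tests against no change, so the general fall alone can make a list pass downward. It also passed downward for p53 targets (fry adjusted p = 0.00633) and ferroptosis defence (0.000421), so it does not set these 2 lists apart. After median-ratio rescaling 17 of 32 and 10 of 20 fell, with 7 and 4 higher, the medians were -1.08 and -1.69, and both lists passed camera (adjusted p = 0.00736 for each). With an estimated correlation, run on the values as deposited, the adjusted p was 0.803 and 0.733.

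The 10 largest falls were mostly genes of these cells. Mpo, the myeloperoxidase of granulocyte precursors, went from 1475 ± 1329 to 4.10 ± 5.77 FPKM (log2 fold change -8.38 ± 0.91, SE, adjusted p = 0.000164). Single libraries weighed on these means: without control replicate 4 the control mean was 901 for Mpo, 491 for Elane and 308 for Ctsg, and without knockout replicate 2 the knockout mean was 0.77 for Mpo and 4.12 for Elane. Knockout means also fell to 0.795 for Dntt and 0.345 for Slc16a11 without replicate 1, and to 3.26 for Cd34, 1.98 for Myl10 and 2.31 for Flt3 without replicate 3. The neutrophil granule proteases Elane, Prtn3 and Ctsg fell by 6.36, 5.98 and 5.69 on the log2 scale, and Dntt, the terminal transferase of early lymphoid cells, fell by 7.48. Cd34 went from 375 ± 21.6 to 6.21 ± 5.75 FPKM and Flt3, a receptor of multipotent progenitors, from 184 ± 36.7 to 3.51 ± 2.20. Slc16a11, Myl10 and Bex6 had log2 fold changes of -5.68, -5.52 and -5.50, with Slc16a11 listed at 0 in knockout replicate 3 and Bex6 in knockout replicate 2. All 10 were also called lower after each of the 3 rescalings.

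Transcripts of the sorting markers did not move together. Kit fell from 137 ± 21 to 12 ± 10.3 FPKM (log2 fold change -3.73 ± 0.45, SE, adjusted p = 0.000123). Procr, a stem cell gene outside the stated gate, fell from 18.7 ± 5.76 to 4.19 ± 2.64. Knockout means were 6.29 for Kit without replicate 3 and 2.73 for Procr without replicate 1. Ly6a, which encodes Sca-1, was at 329 ± 15.0 and 330.2 ± 55.9 FPKM (adjusted p = 0.965) as deposited, but was higher after median-ratio rescaling by 0.96 (adjusted p = 0.000584). Slamf1, which encodes CD150, was at 4.45 ± 0.793 and 3.17 ± 1.71 FPKM (adjusted p = 0.18), and its log2 fold change of -0.48 was 0.27 after rescaling. Cd48 was at 232 ± 72.3 and 240 ± 37.0 FPKM (adjusted p = 0.757), and higher after median-ratio rescaling by 1.07 (adjusted p = 0.00849).

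**Figure D2:**
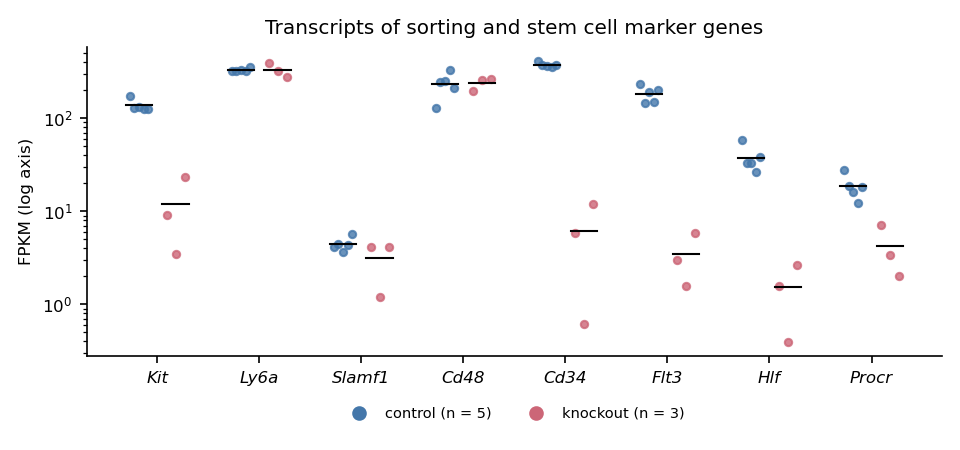
FPKM on a log axis of 8 genes that encode sorting markers or mark stem and progenitor cells; points are libraries (5 control, 3 knockout) and horizontal lines are group means. Kit, Cd34, Flt3, Hlf and Procr do not overlap between the groups, while Ly6a, Slamf1 and Cd48 overlap as deposited.

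Markers of macrophages, of T and NK cells, and of stromal and endothelial cells rose. Of 13 macrophage markers 12 rose and 1, Cd163, did not pass (12 adjusted over the list alone; median log2 fold change 3.17). C1qa, a subunit of complement C1q made by macrophages, went from 106 ± 21.9 to 1069 ± 665 FPKM, the phagocytic receptor gene Axl from 11.8 ± 0.925 to 156 ± 97.0, the mannose receptor gene Mrc1 from 5.91 ± 1.10 to 87.2 ± 54.8, and Cd5l from 2.06 ± 0.363 to 150 ± 109. Of 15 T and NK cell markers 14 rose (15 adjusted over the list alone; median 1.77), among them Cd3e, a T cell receptor subunit, from 18.0 ± 9.91 to 82.1 ± 36.1 FPKM, Thy1 from 9.93 ± 5.35 to 48.0 ± 10.8, Cd4 from 7.62 ± 0.973 to 20.6 ± 7.27 and the granzyme gene Gzmb from 14.6 ± 6.95 to 84.3 ± 20.3. Of 12 stromal and endothelial markers 9 rose and 2 fell, also adjusted over the list alone (median 2.49). The largest rise of all named genes was of Cxcl12, the chemokine of the stem cell niche, from 0.978 ± 0.416 to 164 ± 36.6 FPKM (log2 fold change 6.38 ± 0.23, SE, adjusted p = 5.81e-07). The matrix protein gene Sparc rose from 2.22 ± 0.937 to 139 ± 74.8, while Pdgfrb fell from 10.7 ± 1.82 to 0.85 ± 0.219. Camera gave adjusted p = 1.82e-16, 2.3e-13 and 1.96e-10 for the 3 lists in that order, and adjusted p = 0.234 for each with an estimated correlation. The controls expressed 13 of 13, 15 of 15 and 5 of 12 measured members at a mean of at least 1 FPKM; of these 5 stromal and endothelial genes 2 rose and 2 fell (median 0.26), so 7 of its 9 rises were of genes below that level in controls, which pass the filter mainly when high in knockouts. Relative to all genes the medians were 3.98, 2.58 and 3.30. After median-ratio rescaling 12, 15 and 10 members were higher, with medians of 4.14, 2.74 and 3.13.

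Further genes with large rises follow, of which Adipoq and Lpl were chosen after their values were seen and no list of adipose genes was tested. Fabp4, a fatty acid binding protein of adipocytes, endothelium and macrophages, rose from 3.89 ± 1.29 to 333 ± 216 FPKM, Adipoq, which encodes adiponectin, from 0.318 ± 0.205 to 37.2 ± 18.1, and Lpl, lipoprotein lipase, from 5.10 ± 1.78 to 124 ± 63.0. Stab2, a scavenger receptor of sinusoidal endothelium, rose from 1.88 ± 1.29 to 133 ± 113 FPKM, and Igfbp7, Cyp4b1 and Ubd rose by 5.17, 5.03 and 4.90 on the log2 scale. Adipoq and Ubd were listed at 0 in control replicate 1. Without knockout replicate 2 the knockout means were 213 for Fabp4, 67.8 for Stab2, 99.5 for Cd5l and 52.8 for Cyp4b1. The spread between the 3 knockout libraries was wide: Stab2 was at 54.3, 263 and 81.2 FPKM in knockout replicates 1 to 3, and Cd5l at 35.4, 252 and 164.

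**Figure D3:**
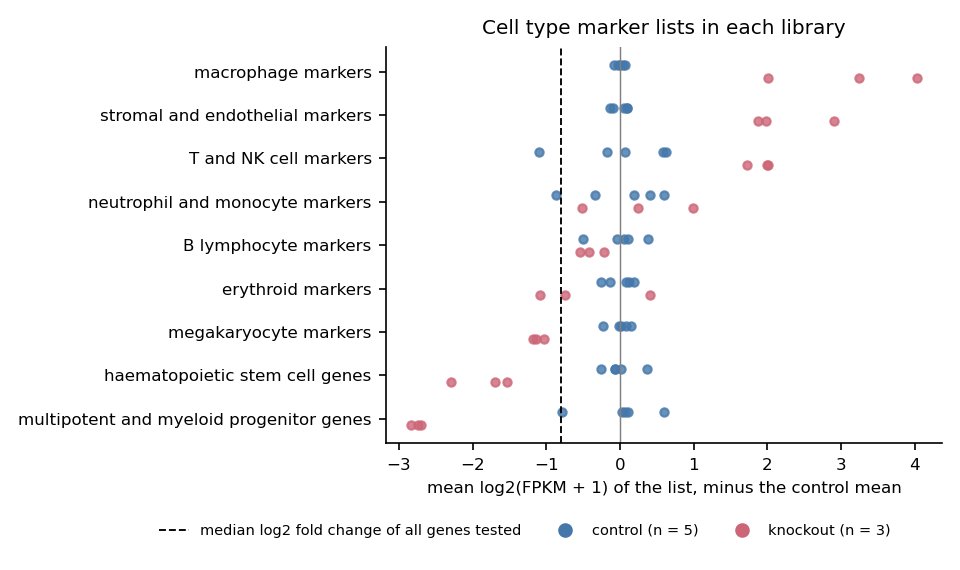
Mean log2(FPKM + 1) of each cell type list minus its control mean, for 5 control and 3 knockout libraries; the dashed line is the median log2 fold change of all genes tested, -0.81. Macrophage, stromal and endothelial, and T and NK cell markers lie to the right of 0 in all 3 knockout libraries, and stem and progenitor genes to the left of the dashed line.

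Markers of other blood lineages moved less or in both directions. Of 18 neutrophil and monocyte markers 1 rose, 2 fell and 15 did not pass (1 and 1 adjusted over the list alone). Cd14 rose from 6.65 ± 3.12 to 19.5 ± 10.4 FPKM, while the receptor gene Csf3r and Chil3 fell by 1.67 and 2.15 on the log2 scale. Leaving out control replicate 2 or 3 or any knockout library ended the call of Chil3 (adjusted p between 0.0529 and 0.126), and its control mean of 189 was 97.3 without control replicate 4. The median of the list, 0.31, lay above that of all genes (camera adjusted p = 0.00141; adjusted p = 0.443 with an estimated correlation; 0.0773 after median-ratio rescaling and 0.664 without a filter). After rescaling 4 were higher and 1 lower. Of 9 B lymphocyte markers 0 rose and 4 fell (3 adjusted over the list alone), with a median of -0.26 that turned to 0.40 after median-ratio rescaling, when 2 were higher and 0 lower. Cd37 and Cd79b fell by 1.27 and 0.72 as deposited. After median-ratio rescaling Cd37 was at -0.30 (adjusted p = 0.287), and Cd79b changed sign to 0.23 (adjusted p = 0.454). Of 14 erythroid markers 3 rose and 5 fell, also adjusted over the list alone, with a median of -0.62 that turned to 0.06 after rescaling, when 4 were higher and 3 lower; without knockout replicate 1 or 2 this list passed camera (adjusted p = 0.0267 and 0.00637). The globin gene Hba-a1 rose from 7.98 ± 4.08 to 63.3 ± 31.8 FPKM, while Car2, carbonic anhydrase, fell from 399 ± 96.9 to 37.9 ± 17.5. Of 17 megakaryocyte markers 12 fell and 2 rose, also adjusted over the list alone (median -1.07), with the platelet glycoprotein gene Gp9 down from 21.6 ± 2.98 to 0.567 ± 0.551 FPKM (0 in knockout replicate 1, and a mean of 0.3 without replicate 3 and 0.85 without replicate 1). After rescaling 5 were lower and 4 higher, with a median of -0.46, so the mostly downward balance depended on the scaling. Of 7 MHC class II genes 0 rose and 2 fell, H2-DMa and H2-DMb1 (median -0.08, and 0.89 after rescaling with 3 higher and 1 lower); without knockout replicate 2 the list passed camera upward (adjusted p = 0.00792). These last 4 lists did not pass camera with the filter and scaling as set; the erythroid list passed upward with the stricter filter (adjusted p = 0.0234) and the megakaryocyte list downward without a filter (0.0022). With an estimated correlation the adjusted p was 0.733 for the erythroid and B lymphocyte lists, 0.803 for MHC class II and 0.914 for the megakaryocyte list.

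Genes of ribosomes, DNA replication and respiration fell. All 60 ribosomal protein genes fell (60 adjusted over the list alone), with a median of -1.76, or -0.95 relative to all genes (camera adjusted p = 2.57e-12; adjusted p = 0.603 with an estimated correlation), and 59 remained lower after median-ratio rescaling. Rpl35 went from 1908 ± 158 to 376 ± 37.8 FPKM and Rpl10a from 1520 ± 144 to 349 ± 34.3. All 30 genes of ribosome biogenesis fell (30 adjusted over the list alone; median -1.57, camera adjusted p = 6.53e-05; adjusted p = 0.327 with an estimated correlation), and 16 after rescaling. Among them Npm1, nucleophosmin, went from 831 ± 118 to 212 ± 24.9 FPKM and Dkc1, dyskerin, from 102 ± 16.6 to 26.8 ± 2.22. Of 34 DNA replication genes 32 fell (32 adjusted over the list alone; median -1.41, camera adjusted p = 0.00145; adjusted p = 0.704 with an estimated correlation), with Mcm7, part of the replicative helicase, down from 131 ± 9.79 to 32.1 ± 1.46 FPKM and Pole, the catalytic subunit of polymerase epsilon, from 25.9 ± 2.99 to 3.27 ± 1.41. After rescaling 14 were lower and 1 higher. Of 40 nuclear-encoded genes of oxidative phosphorylation 39 fell (40 adjusted over the list alone; median -1.10, camera adjusted p = 0.000194; adjusted p = 0.704 with an estimated correlation), and 2 after rescaling, when the camera call ended (adjusted p = 0.0954). Uqcrc2 went from 110 ± 9.07 to 39.5 ± 3.47 FPKM, opposite in direction to the mitochondrially encoded respiratory genes.

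Of 34 mitosis genes 31 fell (32 adjusted over the list alone; median -1.37), including Kif23 from 32.0 ± 5.98 to 10.2 ± 1.74 FPKM, and 3 after rescaling (camera adjusted p = 0.08; 0.0242 without control replicate 1, 0.0248 without knockout replicate 1, 0.00736 after rescaling and 9.85e-10 without a filter; 0.803 with an estimated correlation). Of 17 glycolysis genes 14 fell (15 adjusted over the list alone; median -1.24, camera adjusted p = 0.0577; 0.0472 without control replicate 5, 1.09e-07 without a filter and 0.666 with an estimated correlation), among them the phosphofructokinase gene Pfkl, and after rescaling 7 were lower and 1 higher. Of 20 genes of cholesterol synthesis 18 fell, also adjusted over the list alone (median -1.05, camera adjusted p = 0.0555; 1.48e-08 without a filter and 0.443 with an estimated correlation), and the regulator genes Srebf2 and Insig1 fell by 2.35 and 1.82 on the log2 scale. After rescaling 5 were lower and 1 higher.

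The fall of Nup214 came with that of other nuclear pore genes. Of 12 genes of the Nup214 subcomplex and its transport partners 11 fell, also adjusted over the list alone, and the export receptor gene Xpo1 did not pass. Nup62 went from 61.3 ± 11.2 to 18.1 ± 3.54 FPKM (log2 fold change -1.71 ± 0.18, SE, adjusted p = 4.03e-05) and Nup88 from 55.4 ± 3.47 to 27.6 ± 3.31 (-0.98 ± 0.13, adjusted p = 0.000114). The mRNA export factor genes Rae1 and Gle1 fell by 1.48 and 1.15. The list median was -0.86, or -0.05 relative to all genes (camera adjusted p = 0.102; 3.14e-06 without a filter and 0.666 with an estimated correlation), and after median-ratio rescaling it was 0.02, with 2 lower, Nup62 and Rae1, and 1 higher, Xpo1. All 22 other nucleoporin genes fell (22 adjusted over the list alone; median -0.96, camera adjusted p = 0.0336; adjusted p = 0.624 with an estimated correlation), and 5 after rescaling. The camera call of this list ended without knockout replicate 2 or 3 (adjusted p = 0.0553 and 0.0654) and after rescaling (0.188). It also ended with the stricter filter (0.247), quantile normalization (0.214), rescaling to the non-mitochondrial total (0.12) and the short-gene covariate (0.0509). Nup37 went from 27.5 ± 3.47 to 5.73 ± 2.78 FPKM and Seh1l from 25.1 ± 3.04 to 7.66 ± 1.39.

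Genes of ferroptosis and iron handling moved in both directions. Of 21 ferroptosis defence genes 4 rose and 14 fell, of 16 ferroptosis driver genes 3 rose and 9 fell, and of 17 iron handling genes 5 rose and 7 fell, each with the same counts adjusted over the list alone. After median-ratio rescaling 5, 5 and 8 were higher and 3, 1 and 3 lower, so the balance of calls turned in each list. Hmox1, the haem oxygenase that frees iron from haem, rose from 17.6 ± 5.12 to 547 ± 266 FPKM (log2 fold change 4.80 ± 0.34, SE, adjusted p = 8.18e-06). Slc40a1, the iron exporter ferroportin, rose from 14.1 ± 0.897 to 288 ± 208 FPKM (179 without knockout replicate 2), and the ferritin genes Ftl1 and Fth1 from 2571 ± 634 to 6831 ± 2939 and from 1754 ± 113 to 3337 ± 1366. The groups overlapped in Fth1, whose call ended without knockout replicate 2 or 3 (adjusted p = 0.0673 and 0.0629). Slc40a1 is also 1 of the 13 macrophage markers. Tfrc, the transferrin receptor, fell from 21.2 ± 2.94 to 4.76 ± 1.22 FPKM. Gpx4, the glutathione peroxidase that repairs lipid peroxides, went from 445 ± 60.0 to 221 ± 52.6 FPKM (log2 fold change -1.02 ± 0.18, SE, adjusted p = 0.000674), which was -0.05 after median-ratio rescaling (adjusted p = 0.84). Prdx6 and Gss, glutathione synthetase, fell by 2.06 and 1.48. Acsl4, which loads membranes with oxidizable lipid, fell by 0.64 as deposited and was at 0.23 after rescaling (adjusted p = 0.302). None of the 3 lists passed camera (adjusted p = 0.77, 0.713 and 0.067), their medians were -0.78, -0.72 and -0.19 (mean of the last 0.01), and all 3 turned after rescaling, to 0.06, 0.20 and 0.58. The iron handling list passed camera upward without knockout replicate 1 or 3 (adjusted p = 0.00347 and 0.041) and with the stricter filter (0.00192), and had an adjusted p of 0.666 with an estimated correlation. Without a filter the defence and driver lists passed downward (0.0136 and 0.0482). At an unadjusted p under 0.05, 5 of the 33 lists passed with an estimated correlation, none of them these 3.

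Interferon, p53 and inflammation lists lay above the median of all genes. Of 40 interferon response genes 6 rose, 8 fell and 26 did not pass, also adjusted over the list alone (median -0.14; camera adjusted p = 0.00145; adjusted p = 0.657 with an estimated correlation and 0.433 without a filter), and after median-ratio rescaling 28 were higher and 1 lower, with a median of 0.77. Ifit3 rose from 6.94 ± 1.42 to 40.3 ± 23.7 FPKM (26.7 without knockout replicate 2) and the chemokine gene Cxcl10 from 5.21 ± 1.33 to 61.2 ± 68.1 (22.3 without that library). Tap1, the peptide transporter, fell from 129 ± 16.2 to 60.6 ± 5.73 as deposited, but its log2 fold change was -0.11 after median-ratio rescaling (adjusted p = 0.588). Cxcl10 was at 12.9, 139 and 31.7 FPKM in knockout replicates 1 to 3, and its log2 fold change of 2.71 was 1.80 without replicate 2. The mean of the interferon list relative to controls was 0.34 in knockout replicate 2 and -0.17 and -0.16 in replicates 1 and 3. Both groups had received pIpC per the protocol. Of 25 p53 targets 4 rose, 8 fell and 13 did not pass (1 and 7 adjusted over the list alone; median -0.30, and 0.49 after rescaling with 10 higher and 1 lower; camera adjusted p = 0.0407; adjusted p = 0.346 with an estimated correlation, 0.237 without genes of 2 or more lists and 0.29 without a filter). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 37.6 ± 6.37 to 52.7 ± 7.69 FPKM (adjusted p = 0.029, between 0.05005 and 0.092 without control replicate 1, 4 or 5 or knockout replicate 2 or 3) and the death receptor gene Fas from 5.39 ± 1.04 to 17.4 ± 7.11, while Sesn1 fell by 1.81. Of 20 NF-kB and inflammation genes 7 rose and 5 fell, also adjusted over the list alone (median 0.38; camera adjusted p = 0.000163; adjusted p = 0.182 with an estimated correlation and 0.415 without a filter), and after rescaling 12 were higher and 2 lower, with a median of 1.10. The chemokine genes Ccl5 and Ccl3 moved apart, Ccl5 from 820 ± 352 to 3734 ± 709 FPKM and Ccl3 from 146 ± 41.2 to 24.5 ± 12.5, and Nfkb1 fell by 1.67.

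The remaining lists did not pass camera with the filter and scaling as set. NRF2 targets passed upward with the stricter filter (adjusted p = 0.00861). Without a filter the apoptosis (0.0176), integrated stress response (0.00256), unfolded protein response (0.000354), heat shock (0.000478) and immediate early (0.000265) lists passed downward. With an estimated correlation the adjusted p of these lists lay between 0.733 and 0.945. Of 22 apoptosis genes 3 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.38; passed upward after quantile normalization, 0.0376, and median-ratio rescaling, 0.0495), with Bcl2a1b up from 15.8 ± 5.29 to 80.7 ± 4.14 FPKM while Birc2 fell by 1.41. Of 18 cyclin-dependent kinase inhibitor and quiescence genes 2 rose and 10 fell, also adjusted over the list alone, among the latter Foxo3 from 15.3 ± 2.65 to 4.30 ± 1.82 FPKM. Of 20 NRF2 targets 5 rose and 10 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.288, and 0.0248 without knockout replicate 1), of 21 integrated stress response genes 2 rose and 13 fell (3 and 13 adjusted over the list alone), of 13 heat shock genes 1 rose and 9 fell, and of 19 unfolded protein response genes 0 rose and 11 fell, the last 2 also adjusted over the list alone. Hsp90ab1, a cytosolic chaperone, went from 1107 ± 94.4 to 366 ± 32.1 FPKM, and Vldlr from 17.3 ± 3.92 to 0.757 ± 0.549 (0.465 without knockout replicate 2). Of 21 immediate early genes 14 fell and 1 rose, also adjusted over the list alone, with Fos from 239 ± 77.6 to 33.0 ± 9.30 FPKM and Jun from 158 ± 59.8 to 23.4 ± 12.8. After median-ratio rescaling the balance turned to 9 higher and 2 lower for apoptosis, 6 and 1 for the quiescence list, 5 and 2 for NRF2 targets, 6 and 4 for the integrated stress response, 3 and 2 for heat shock and 5 and 0 for the unfolded protein response, and was 4 and 4 for immediate early genes. Of these 7 lists the medians of 6 lay below 0 as deposited and above 0 after median-ratio rescaling, and that of the immediate early genes was -1.05 and -0.09. Camera gave the unfolded protein response and integrated stress response lists a downward direction although their medians lay 0.22 and 0.06 above that of all genes. The unfolded protein response list passed camera upward after quantile normalization (adjusted p = 0.0177) and median-ratio rescaling (0.0268).

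**Figure D4:**
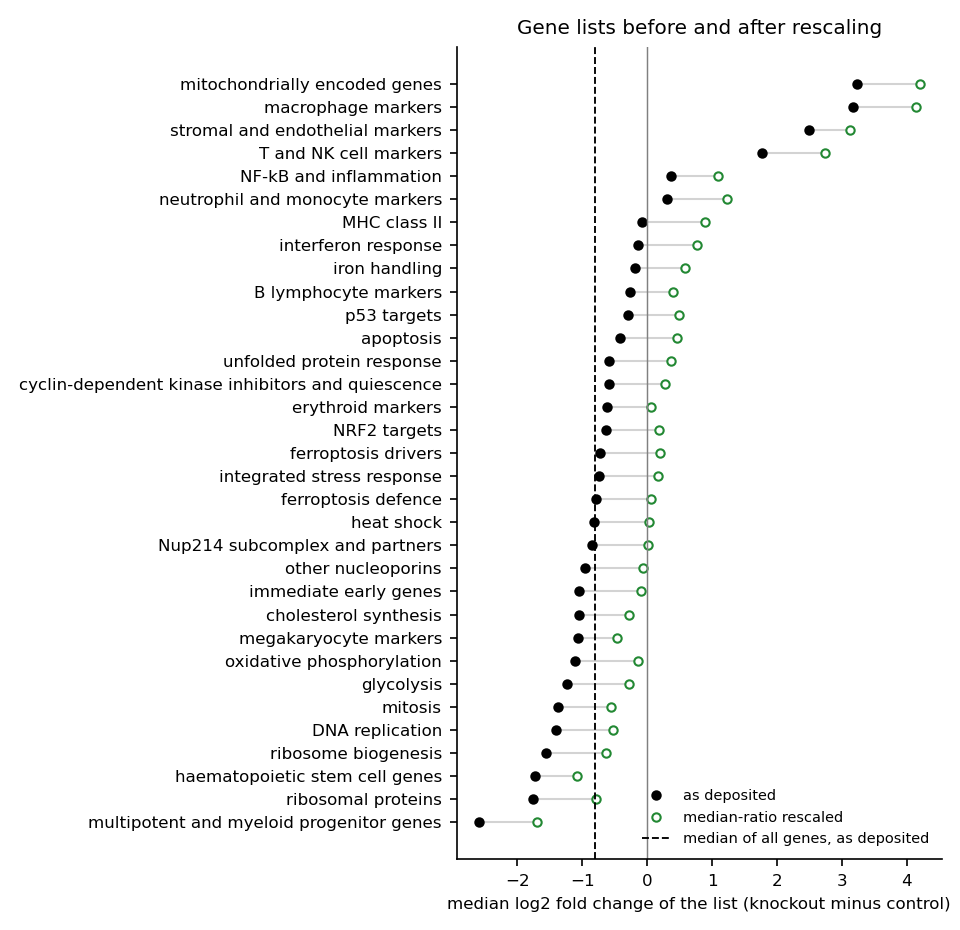
Median log2 fold change (knockout minus control) of the 33 gene lists as deposited (filled points) and after median-ratio rescaling (open points); the dashed line marks the median of all genes as deposited, -0.81. The mitochondrial, macrophage, stromal and endothelial, and T and NK cell lists stay above 0 on both scales, and the stem, progenitor, ribosomal and replication lists below 0, while lists with a deposited median between -0.86 and -0.08 change sign.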

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

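The tests of the mitochondrial share, of an equal rise of all other cells, of an even gain of mitochondrial genes, of further-list genes expressed in controls, with reticular and fibroblast genes set apart, of nuclear-retained RNA, of nuclear-encoded respiratory genes and the split count for genes were chosen only after the results they measure had been seen. The genes of the further cell type lists, the iron genes' link to macrophage genes, the vomeronasal receptor genes and the split count for lists were set before their results were seen.

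A control library lay far from the other 4 controls, by a gap test on the range at the 95% level, in 14 of 170 measures, and chance gives about 1 in 20. Control replicate 1 stood apart in 7. The most abundant ribosomal RNA gene took 11.5% of its FPKM, against 5.40% to 6.54% in the other controls. Its FPKM was 1.61 for Fabp4 (others 4.14 to 4.72), 7.88 for Mrc1 (5.29 to 5.54), 174 for Kit (124 to 132), 0.31 for Gzma (64.3 to 92.4) and 0.64 for Cldn5 (1.87 to 2.5). Its mean log2(FPKM + 1) over the Nup214 subcomplex list was 4.57 (others 4.65 to 4.67). Control replicate 4 stood apart in Nup107 at 24.8 FPKM (others 18.3 to 19.8), Kif23 at 42.5 (27.8 to 30.5), Tkt at 367 (241 to 263), and in the mean log2(FPKM + 1) of the glycolysis list at 6.97 (6.57 to 6.67) and of the NRF2 list at 6.4 (6 to 6.1). Control replicate 5 stood apart in Gp9 at 16.5 FPKM (21.8 to 23.6) and Apoe at 673 (944 to 1008). No explanation was tested for these single libraries, and the knockout group, with 3 libraries, was not tested this way.

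The first pattern weighed was the fall of stem and progenitor genes with a rise of macrophage, T and NK, and stromal and endothelial genes. The larger mitochondrial share of FPKM, which lowers every other gene alike, was argued against as the whole cause by the progenitor median of -1.86 after rescaling to the non-mitochondrial total. For an equal rise of all other cell types around fewer stem cells, the macrophage median exceeded the B lymphocyte median by 3.43 (permutation p = 0.00211, 100000 resamples of members). This p treats member genes as independent, although the macrophage list had an estimated correlation of 0.817, and it does not measure the spread between libraries. The controls expressed all 9 measured B lymphocyte markers at a mean of at least 1 FPKM. A fall of the control cells' own transcripts could hide an added B cell signal, so the gap does not decide against an equal rise. In knockout replicates 1 to 3 the macrophage mean relative to controls was 2.01, 4.03 and 3.24, and the B lymphocyte mean -0.22, -0.55 and -0.42. Macrophages, T or NK cells and endothelial cells in the knockout sorts may be a source: among members that controls expressed at a mean of 1 FPKM or more, 3 of 3 further lists had medians of 1.97, 1.63 and 1.36, at percentile 100 of 10000 random lists matched on control mean, with 0 of their genes in the first lists. For reticular cells and fibroblasts the median of such members was 0.23 (percentile 99.81) with genes moving both ways, so these cells cannot be told apart from other sources. Random lists hold unrelated genes, whereas genes of a cell type move together, so all these percentiles overstate how rare such medians are. The further lists also rest on the same 8 libraries as the first lists. The lineage-negative, CD48-negative gate should remove macrophages and T cells, and stem cells that change their own expression after Nup214 loss remain open and untested.

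The medians just given rest on 16 of 18 macrophage genes (13 rose, 0 fell), 20 of 20 T and NK genes (15 rose, 1 fell), 10 of 16 endothelial genes (7 rose, 2 fell) and 6 of 11 reticular and fibroblast genes (2 rose, 1 fell). The most abundant macrophage genes among them in knockouts, Apoe, Ctsd and Ctsb, were at 3103 (1838 without knockout replicate 2), 1527 and 1285 FPKM. Further lists of B lymphocyte genes (11 of 13 expressed in controls, 1 rose, 7 fell) and neutrophil genes (16 of 18, 2 rose, 3 fell) had medians of -1.13 and -0.58, at percentiles 17.1 and 95.7.

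The second pattern was the rise of mitochondrial genes. DNA in the libraries as the whole cause was argued against, because an even gain made up 7.61% of the summed gain of the 13 genes (6.65% to 8.39% over knockout libraries), from 1270 FPKM for mt-Nd4l to 37826 for mt-Co1. A larger respiratory programme was argued against by the nuclear-encoded genes, whose median lay at -0.30 relative to all genes. Loss of cytoplasmic RNA from damaged cells that keep nuclear and mitochondrial RNA alike was argued against as the whole cause: 13 nuclear-retained RNAs had a median of -0.0337 relative to all genes (interquartile range 2.16) and none was above 2.71, against 4.04 for the mitochondrial genes. The nuclear-retained RNAs moved both ways, 4 higher and 7 lower, and their levels may also reflect which cells were collected. A partial loss remains open. DNA may still be a part of the knockout libraries: olfactory receptor genes, which marrow cells are not known to use, were 7.29 times as high, and vomeronasal receptor genes, 292 in all, were 8.77 times as high (3.37 to 20.5 FPKM in controls, 77.8 to 94.2 in knockouts), at 0.302 against 0.407 FPKM per gene.

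The third pattern was the rise of some iron and ferroptosis genes. As deposited, more members of each of their 3 lists fell than rose, but so did all genes (8997 lower, 1348 higher). After median-ratio rescaling the balance turned in each list. Of the 7 called-higher members outside the macrophage list (Alox5, Fth1, Ftl1, Hfe, Hmox1, Hspb1 and Sat1), 71.4% followed the macrophage list over the 3 knockout libraries (Pearson r above 0.9), against 28.5% of 1329 other called-higher genes (Fisher's exact p = 0.0236). Macrophage RNA may account for part of this rise, but 3 libraries make each such r imprecise. Fisher's test also counts the genes as independent, although all rest on the same 3 libraries. The stromal and endothelial list, like the macrophage list, was lowest in knockout replicate 1 and highest in replicate 2. The T and NK list was lowest in replicate 2. The test therefore cannot tell macrophage RNA apart from stromal or endothelial RNA. Expression of these iron and ferroptosis genes by knockout stem cells was not tested and remains open.

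With the 8 libraries split into 5 and 3 in all 56 ways, 1 split, the real one, gave as many as 10345 genes, and the highest other gave 15. A share of 1 in 56 is the smallest that this test can give, so chance is unlikely but not excluded for the gene count. Every other split mixes the groups, so the group difference adds to its spread and lowers its count of genes. The 10345 genes are those of the values as deposited. For the 13 gene lists, 14 of the 56 splits gave as many and the highest other gave 17. That count came from control replicate 1 with knockout replicates 2 and 3, and from control replicates 3 to 5. Such splits keep the knockouts mostly or wholly together and so still hold part of the group difference. The list count therefore neither excludes chance nor measures it.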

How the results depend on the processing

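Rescaling to the non-mitochondrial total, the short-gene covariate and leaving out genes under 300 nt were chosen only after the results had been seen. Apart from the counts and Nup214, alternatives left direction and call as they were in 3196 values, ended a call in 113 (60 falls and 27 rises of genes, 14 downward and 12 upward lists), made one in 41 (5 rising genes, 25 downward and 11 upward lists) and reversed 21.

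Quantile normalization gave 5609 changed genes (2530 higher, 3079 lower), 4419 of them shared with the same direction. Median-ratio rescaling gave 5397 (2877 and 2520; 3866 shared), and rescaling to the non-mitochondrial total 5723 (2310 and 3413; 4732 shared). Their medians of all genes were -0.11, -0.02 and -0.17. Nup214 was at -0.72 after median-ratio rescaling (adjusted p = 0.0538, between 0.000195 and 0.0538 over all alternatives). No filter gave 3561 higher genes and 23 lists, and the stricter filter 619 higher, with other genes tested. Requiring at least 2-fold left 6843 genes, 5782 lower, and testing against 1.5-fold left 5711 (830 higher, 4881 lower), both stricter by construction. With an estimated correlation limma's camera called 0 lists, 5 at an unadjusted p under 0.05. The replicate block gave 8839 genes and ended the calls of Apoe (adjusted p = 0.0712), Cdkn1a (0.133), Acsl4 (0.112), mt-Tn (0.175), Gzma (0.128), Fcrla (0.112) and the other nucleoporins list (0.0638), while the glycolysis list passed (0.0316).

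Leaving out each library gave 847 to 1351 higher genes (lowest without knockout replicate 2, and 860 without 3), 8379 to 8792 lower and 13 to 17 lists, and Nup214 between -1.80 and -1.38. The filter still asked for 3 libraries, so leaving out a knockout library also removed genes expressed only in knockouts.

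Reversed genes, under quantile normalization, were Cd79b (0.18), Herpud1 (0.00595), Dnajb9 (0.0828), Ly6a (0.79) and Acsl4 (0.16); under median-ratio rescaling Cd79b (0.23), Herpud1 (0.0621), Canx (0.0309), Dnajb9 (0.13), Ly6a (0.96) and Acsl4 (0.23); and under non-mitochondrial rescaling Cd79b (0.0545), Ly6a (0.79) and Acsl4 (0.0743). All 3 raised the median log2 fold change of all genes. Without a filter the lists of ferroptosis defence (adjusted p = 0.0136), ferroptosis drivers (0.0482), p53 targets (0.290), interferon response (0.433) and apoptosis (0.0176) turned downward. The unfolded protein response turned upward under quantile normalization (0.0177) and median-ratio rescaling (0.0268). Without a filter 42237 genes were tested, with a median log2 fold change of 0.05, against -0.81 with the filter. Camera thus compared lists with a higher background, which goes with the downward turns. No further cause was tested for the lists. Depth limits genes under about 0.0619 FPKM per fragment at 1 kb in the shallowest library.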

Other observations

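The position of Nup214 among genes of like expression was tested only after its fall had been seen.

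Control libraries held transcripts that the CD48-CD150+ gate would be thought to exclude or lower: Cd48 at 232 ± 72.3, Flt3 at 184 ± 36.7, Dntt at 537 ± 105 and Mpo at 1475 ± 1329 FPKM, with Slamf1 at 4.45 ± 0.793 (SD, n = 5). In knockouts Apoe was at 3103 ± 2308 FPKM (SD, n = 3) against 918 ± 139 in controls, Ctsd at 1527 ± 798 against 266 ± 24.8 and Ctsb at 1285 ± 737 against 277 ± 48.6. Apoe was at 1113, 5633 and 2563 FPKM in knockout replicates 1 to 3; its log2 fold change of 1.47 was 0.89 without replicate 2. Spearman correlations over all genes were 0.818 to 0.881 within controls, 0.723 to 0.728 within knockouts and 0.704 to 0.755 between them, across genes, which are not independent replicates. The first principal component held 65.1% of the variance and the second 9.13%.

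A hypothesis was that recombination of the floxed gene lowers Nup214 beyond the general fall. Nup214 lay at percentile 18.2 of the 500 genes nearest in control mean, between the 5th percentile that the hypothesis needed and the median that would have argued against it, so the data leave it open. The values per gene could not show the deleted exons.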
